A study of Mus musculus with 39 samples.

How the data were processed

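Gene expression was measured by RNA sequencing in intact 2-cell and 4-cell mouse embryos and in the single blastomeres of separated embryos, with total RNA, oligo-dT priming, template switching, PCR and tagmentation. According to the submitters, reads were trimmed with Trim Galore 0.6.10, aligned with STAR 2.7.3a to GRCm38 and quantified with RSEM 1.2.28. The authors deposited expected counts per gene, of which 12.6% of the non-zero values are not whole, and these were rounded to whole numbers. The labels do not state the annotation or the strandedness. Of 55487 genes, 53170 matched 1 entry of GENCODE M21, 234 were named by ID and symbol, and 29371 had a count. No pair of libraries was identical and no column was left unused.

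The counts of the blastomeres of an embryo were summed, which gave 19 embryos in 4 groups. The main test was the edgeR 4.0.16 quasi-likelihood F-test with TMM scaling, filterByExpr (14119 genes), the 4 groups and batch as terms, all embryos in 1 fit and Benjamini-Hochberg adjustment at 0.05. The contrasts were the stage in intact and in separated embryos, separation at each stage, their interaction and batch. Because batch 2 holds separated 4-cell embryos only, the 4-cell separated level is that of batch 1. The standard error is the absolute log2 fold change over the square root of F. The biological coefficient of variation was 1.43, with 14 residual and 5.75 prior degrees of freedom. CPM of embryos and means over the sisters of an embryo are TMM-normalised, and CPM of single blastomeres, of Y-linked genes and of markers of other cells are per total counts of the library.

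For embryo differences, blastomeres were libraries and the embryo a factor in the edgeR test, with differences tested within a batch. Sister similarity is the mean Pearson correlation of log2 CPM (prior count 2, genes of mean CPM at least 10) between sisters minus that between embryos of the same batch, with exact or 100000 random regroupings of blastomeres. Variability between sisters is the pooled variance within embryos minus its lowess trend (span 0.3) on mean level, and a list's median was ranked among 10000 lists matched in 20 expression bins.

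Lists of genes (23) were written before the data were examined: maternal oocyte transcripts, zygotic 2-cell genes, lineage and pluripotency regulators, ribosome biogenesis, ribosomal proteins, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, proteasome, histones, immediate early and stress genes, heat shock, p53 targets, Hippo and YAP, adhesion and polarity, G2/M, S phase, chromatin and DNA methylation, cholesterol and lipids, sex-linked genes, and markers of cumulus and granulosa cells, blood, sperm and oviduct. The 20 lists with 5 or more genes tested entered limma 3.58.1 camera with a preset correlation of 0.01, adjusted over lists and 4 contrasts, and an estimated correlation and fry were alternatives.

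Genes named are, per stage or separation contrast, the 8 highest and 8 lowest log2 fold changes among genes with adjusted p under 0.05, mean CPM of at least 10, embryo groups that do not overlap and a symbol other than a predicted one, plus up to 3 members of each list with the smallest p. For embryo differences and sister variability they are the 8 first genes of mean CPM at least 50. A fold against a group without counts is a bound with 3 counts set for the group, and against 1 to 3 counts a ratio with its counting interval.

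Alternatives were the DESeq2 size factors, other count filters, a fit of the compared groups alone, the replicate number as a block, thinning of totals (to 2.74 M counts per embryo, in units of 1e+06) or of sisters, DESeq2 1.42.0, limma voom with quality weights, each blastomere as a library with limma duplicateCorrelation, no batch term, batch 2 left out, each embryo left out, Spearman correlation, a prior count of 0.5 and CPM limits of 1 and 100. The edgeR, camera, embryo and sister tests were tested on simulated data, with 200 changed genes for edgeR. Unusual values were sought with Dixon's test at 95%. Clustering of cells, splicing, isoforms and alleles were left out, since only counts per gene were at hand. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3 were used.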

Results

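Transcripts of wild-type mouse embryos were measured in 39 libraries, each made from 1 whole embryo or from 1 blastomere. They come from 19 embryos: 5 intact and 5 separated 2-cell embryos, and 4 intact and 5 separated 4-cell embryos. The comparisons ask how expression differs between the stages, whether embryos taken apart differ from intact ones, and how alike the blastomeres of an embryo are. The embryo is the replicate, and the counts of its blastomeres were summed. An intact embryo is 1 library, while a separated embryo is a sum of libraries made from single blastomeres. An effect of separation therefore cannot be told apart from one of input per library or of the number of libraries summed. Counts per embryo were also higher in separated than in intact embryos of each stage. The labels do not say that the embryos come from separate animals or litters, so a p-value measures the spread between these embryos, which may be partly technical. They also do not say whether, or for how long, blastomeres were cultured after separation.

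In intact embryos, the pioneer transcription factor Foxa1 had no count at the 2-cell stage (n = 5) and 55.5 ± 16.8 CPM at the 4-cell stage (mean ± SD, n = 4), a rise of at least 745-fold (edgeR adjusted p = 6.41e-05). Sox21, an SRY-box factor of the early embryo, rose at least 444-fold, from no count to 33.1 ± 21.7 CPM (adjusted p = 0.00104). The ribonuclease H2 subunit gene Rnaseh2b rose at least 560-fold (41.7 ± 11.3 CPM, adjusted p = 0.00324), and the kinase gene Mast3 at least 395-fold (29.4 ± 4.39 CPM, adjusted p = 0.000179). Ccdc93, Rbm41 and Trim39 rose by bounds of 397, 375 and 365-fold. Id3, an inhibitor of DNA binding by helix-loop-helix proteins, went from 1 count to 641 counts, 40.6 ± 49.1 CPM, a ratio of 1787 (counting interval 319.7 to 70710, adjusted p = 0.00307). Trim39 did not pass without intact 2-cell embryo 1, 2, 3 or 4 or without intact 4-cell embryo 1, 3 or 5, with an adjusted p of up to 0.0628.

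Among the genes that fell, Zscan4f, a zinc finger gene whose expression marks the 2-cell stage, went from 63.0 ± 61.0 CPM to 1 count, a ratio of 848 (152.1 to 33510, adjusted p = 0.000316). Gtsf2 fell from 65.3 ± 25.3 CPM, with 110 CPM in intact embryo 2, to 1 count, a ratio of 895 (160.4 to 35360, adjusted p = 0.000364). AA536875 and the immunoglobulin constant region gene Iglc3 also fell to 1 count, by ratios of 766 (137.4 to 30280) and 690.0 (123.7 to 27270). Mfap2, a component of extracellular microfibrils, was at 47.2 ± 53.7 CPM in intact 2-cell embryos and had no count at the 4-cell stage, a fall of at least 227-fold (adjusted p = 0.01). Pate14, the galactosyltransferase gene B4galt4 and the oligoadenylate synthetase gene Oas1h fell at least 135, 109 and 102-fold. Oas1h did not pass without intact 4-cell embryo 1, 3, 4 or 5 (adjusted p of up to 0.0647). The intervals and the bounds, which set a group without counts at 3 counts, cover counting error only, since these are PCR-amplified reads without molecular tags.

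Genes were grouped into lists fixed before the data were examined. Of 63 maternal oocyte transcripts, 30 fell and 1 rose from the intact 2-cell to the intact 4-cell embryos (median log2 fold change −3.02, or −2.91 with genes without counts at their bound). Omt2a fell from 17630 ± 5604 to 588 ± 98.7 CPM, a log2 fold change of −4.91 ± 0.42 (SE, adjusted p = 1.66e-06). Tcl1, a coactivator of the kinase AKT, fell by −6.63 ± 0.60, and Btg4, an adaptor that recruits the deadenylase clearing maternal messages, by −3.89 ± 0.41 (1189 ± 532 to 80.4 ± 10.7 CPM). Of 34 zygotic genes expressed at the 2-cell stage, 16 fell and 0 rose (median −3.66, with bounds −3.54). Rfpl4b fell from 1038 ± 168 to 6.78 ± 3.97 CPM (−7.27 ± 0.65, adjusted p = 1.66e-06), and the homeobox gene Obox3 from 500 ± 145 to 6.22 ± 4.75 CPM. Counts adjusted over the list alone were 39 lower and 2 higher for the maternal list and 19 lower and 3 higher for the zygotic list. With limma camera the adjusted p was 3.34e-16 for the maternal and 7.43e-10 for the zygotic list. The maternal call held, with adjusted p = 0.0216 with an estimated correlation, and the zygotic call did not (adjusted p = 0.145 with an estimated correlation).

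Of 78 ribosomal protein genes, 65 rose and 0 fell (median 1.49), though the list did not pass with an estimated correlation (adjusted p = 0.452). Rpl36 rose from 49.8 ± 22.9 to 334 ± 62.0 CPM (log2 2.75 ± 0.39, adjusted p = 0.00022), Rpl32 by 2.16 ± 0.32 and Rps29 by 1.91 ± 0.27. Of 99 ribosome biogenesis genes, 16 rose and 1 fell (median 0.85), among them the nucleolar proteins Npm1 (1566 ± 460 to 4886 ± 705 CPM, log2 1.64 ± 0.27), Nolc1 (1.82 ± 0.30) and the RNA helicase gene Ddx21 (2.08 ± 0.36). Of 80 nuclear genes of oxidative phosphorylation, 16 rose and 6 fell (median 0.75). Cox7c rose by 2.99 ± 0.55 and Atp5k by 1.93 ± 0.34, while Cox6b2, the testis-type subunit of cytochrome c oxidase, fell from 1225 ± 541 to 121 ± 38.5 CPM (−3.34 ± 0.46, adjusted p = 0.000146). Proteasome genes rose in 8 of 35 cases and none fell (median 1.13), with Psmc1 at 2.60 ± 0.56 and Psmb4 at 2.19 ± 0.46. Of 43 replication-dependent histone genes, 6 rose and 0 fell (median 1.35, with bounds 1.34), among them H4c4 (57.4 ± 23.7 to 819 ± 469 CPM, 3.83 ± 0.50) and H1f5 (4.21 ± 0.68). Here and in separated embryos, the histone values cover only transcripts that oligo-dT primed, which need not follow the total of histone messages. Of 39 lineage and pluripotency regulators, 7 rose and 0 fell (median 0.91). Beside Sox21, the nuclear receptor gene Nr5a2 rose from 43.7 ± 11.03 to 254 ± 76.9 CPM (2.54 ± 0.37) and Dppa2 by 2.16 ± 0.40.

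Adjusted over the list alone, these counts became 76 higher for ribosomal proteins, 18 higher and 1 lower for ribosome biogenesis, 19 higher and 9 lower for oxidative phosphorylation, 14 higher for the proteasome, 11 higher for histones and 10 higher for lineage regulators. All 6 lists passed camera as higher, with adjusted p of 9.94e-18, 4.39e-05, 0.0112, 0.000353, 0.0041 and 0.00226 in that order. With an estimated correlation the lineage list alone held (adjusted p = 0.026 with an estimated correlation), and the other values were 0.452, 0.37, 0.452, 0.145 and 0.599. The DESeq2 size factors moved the median of all genes by −0.12, and all 8 lists kept their direction, with ribosomal proteins at 1.38.

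The remaining lists did not pass camera in intact embryos, though single members did. Of 44 heat shock genes, 10 rose and 2 fell (adjusted p = 0.33), and the chaperone genes Hspa8 and Hsp90ab1 rose by 3.30 ± 0.44 (37.5 ± 11.2 to 369 ± 124 CPM) and 3.26 ± 0.50. In the G2/M list 3 of 52 rose and 4 fell (adjusted p = 0.998). Cks1b fell by −1.68 ± 0.25, the securin gene Pttg1 by −1.81 ± 0.31 and the spindle gene Nusap1 by −1.87 ± 0.34. The S phase list had 4 higher and 3 lower of 62 (adjusted p = 0.469), with the replication licensing gene Cdc6 up 2.42 ± 0.44, though intact 4-cell embryo 4 was at 57.9 CPM against 216.2 to 242.9 CPM in the others. Of 28 cholesterol and lipid genes, 2 rose and 1 fell (adjusted p = 0.985). The sterol sensor gene Insig1 fell by −4.67 ± 0.70. Of 80 chromatin and DNA methylation genes, 2 rose (adjusted p = 0.152), among them the methylcytosine dioxygenase gene Tet1 (2.68 ± 0.60, adjusted p = 0.00758). Of 27 mitochondrially encoded genes, mt-Nd2 alone passed, falling by −0.95 ± 0.19 (list adjusted p = 0.812).

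Adhesion and polarity had 2 higher and 2 lower of 43 (adjusted p = 0.952), and the connexin gene Gja1 rose by 2.73 ± 0.70, a call lost without intact 4-cell embryo 1 or 5 (adjusted p up to 0.0638). Hippo and YAP genes had 2 lower of 26 (adjusted p = 0.755), p53 targets 2 higher of 31 (adjusted p = 0.937), and immediate early and stress genes 1 higher of 26 (adjusted p = 0.641). None of 5 sperm genes (adjusted p = 0.323) and none of 5 sex-linked genes (adjusted p = 0.998) passed. Adjusted over the list alone, the counts higher and lower were 11 and 2 for heat shock, 3 and 5 for G2/M, 4 and 3 for S phase, 2 and 1 for cholesterol, 2 and 0 for chromatin, 2 and 2 for adhesion, 1 and 2 for Hippo, 1 and 0 for sex-linked genes and 0 for p53 and stress genes. The median, the mean and the test differed in sign for p53 targets (median −0.61, −0.41 with bounds, mean −0.28, test higher), adhesion (0.31, −0.21, lower), G2/M (0.01, −0.07, higher), cholesterol (−0.16, 0.30, higher) and sex-linked genes (−0.68, 0.98, lower). The G2/M median was −0.12 with the DESeq2 size factors.

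**Figure D1:**
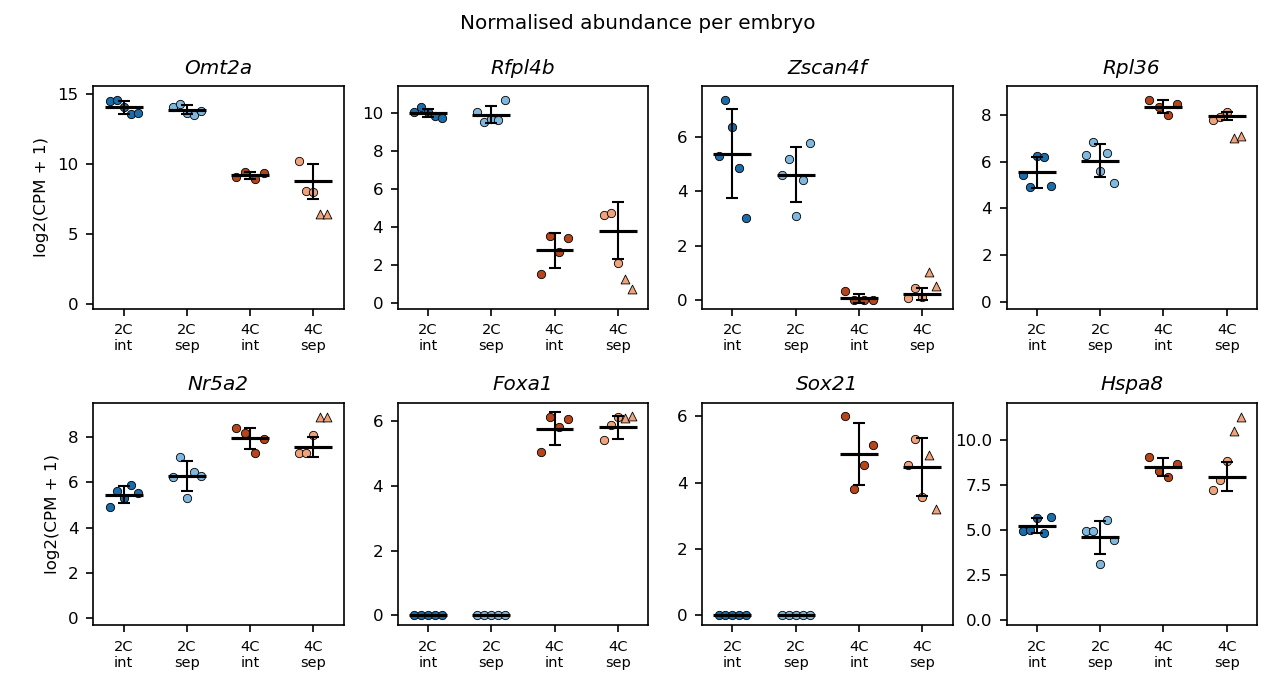
Level of 8 genes, as log2 of TMM-normalised CPM plus 1, per embryo in the 4 groups, with circles for batch 1 and triangles for batch 2 embryos and a line and bar for the mean ± SD of the batch 1 embryos. Omt2a, Rfpl4b and Zscan4f are lower, and Rpl36, Nr5a2, Foxa1, Sox21 and Hspa8 higher, at the 4-cell stage, with Foxa1 at 0 in intact 2-cell embryos and 55.5 CPM in intact 4-cell embryos.

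In total 1469 of 14119 genes passed between intact stages (edgeR, 764 higher and 705 lower), 1443 of them by over 2-fold. The count went to 737 with the replicate block, 715 with each blastomere as a library, 2844 with limma voom and 3047 with DESeq2. The share higher, 52.01%, depended on the setting: it was 46.7% with the DESeq2 size factors, 45.5% with the stricter filter, 41.7% with DESeq2, 38.0% with the compared groups alone and 64.3% with limma voom. In 1198 of the genes called no 2-cell embryo overlapped any 4-cell embryo. Chance gives this for 1.59% of unselected genes, which is no measure for genes picked for a stage difference. The count was 798 without intact 4-cell embryo 5, 808 without embryo 3 and 898 without embryo 1. In simulated data 0% of genes changed 2-fold, 24% of those changed 4-fold and 42% of those changed 16-fold were recovered, so most simulated changes of these sizes were missed. With limma voom many abundant genes did not pass, Omt2a (adjusted p = 0.586), Btg4, Tcl1, Hspa8, Npm1, Dppa2 and mt-Nd2 among them, and of 45 list examples 8 passed in every setting against 13 of the 16 genes with the largest changes.

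Embryos that had been separated gave a like picture. Foxa1 again went from no count (n = 5) to 55.8 ± 13.8 CPM (n = 3, batch 1), at least 3459-fold (adjusted p = 5.57e-05). Fbp2, a fructose bisphosphatase gene, rose at least 3423-fold (55.2 ± 25.4 CPM, adjusted p = 0.000106), and the phosphatase-binding protein gene Igbp1 at least 3640-fold (58.7 ± 41.4 CPM, adjusted p = 0.000786). Mrps18a, a subunit of the mitochondrial ribosome, went from 2 counts to 5737 counts, 133 ± 30.2 CPM, a ratio of 12030 (3328 to 99330). Dynap, Sycn, Crygs and Dydc2 rose by bounds of 3361, 2931, 2510 and 2430-fold. The DNA helicase gene Pif1 fell from 25.2 ± 11.4 CPM to no count, at least 374-fold (adjusted p = 0.00573), and the centromere protein gene Cenpv at least 357-fold (24.1 ± 21.96 CPM, adjusted p = 0.000504). Rundc3b and the zinc finger gene Glis3 fell at least 346 and 324-fold. Creb3l4 (ratio 2073, 372.1 to 81910), Nabp2 (1122, 201.2 to 44320) and Ssmem1 (970, 174.0 to 38330) fell to 1 count and Fbxw4 (850, 290.9 to 4124) to 3 counts. Creb3l4 did not pass without separated 4-cell embryo 2 or 4 (adjusted p up to 0.0553, log2 fold change −10.43 and −10.46 against −10.92), and Ssmem1 not without 2 or 3 (0.0674, −9.27 and −9.26 against −9.78). Nabp2 (adjusted p up to 0.104, −9.01 to −12.27 against −9.83) and Fbxw4 (0.119, −9.19 to −13.57 against −9.73) did not pass without 2, 3 or 4 or without separated 2-cell embryo 2, for Fbxw4 also embryo 1.

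By list, 28 of 63 maternal transcripts fell and 0 rose between the separated stages (median −3.09). Omt2a fell from 14970 ± 3364 to 562 ± 525 CPM (−4.73 ± 0.48), Btg4 by −4.96 ± 0.49 and the homeobox gene Obox5 by −5.57 ± 0.57, each at adjusted p = 1.3e-05. Of the zygotic 2-cell genes, 18 of 34 fell and 0 rose (median −5.06), with Rfpl4b at −5.87 ± 0.69 and Obox3 at −6.87 ± 0.91. Ribosomal proteins rose in 67 of 78 cases with 0 lower (median 1.52), among them Rpl21 (280 ± 34.9 to 1044 ± 116 CPM, 1.90 ± 0.27), where separated 2-cell embryo 5 was lowest at 219 CPM, and Rpl41 (1.35 ± 0.20). Ribosome biogenesis genes had 17 higher and 3 lower of 99 (median 0.78), with Wdr75 up 1.88 ± 0.37. Of 80 nuclear genes of oxidative phosphorylation, 18 rose and 2 fell (median 1.06), with Ndufs5 up 4.09 ± 0.53, Atp5k up 2.40 ± 0.36 and Cox6b2 down, at −4.65 ± 0.56. Proteasome genes rose in 9 of 35 cases (median 1.21), with Psma6 at 1.94 ± 0.44 and Psmb2 at 1.43 ± 0.30, and histone genes in 7 of 43 (median 1.44), with H4c4 at 4.07 ± 0.52. Of 39 lineage regulators, 9 rose and 2 fell (median 0.96, with bounds 1.03). Sox21 rose at least 1481-fold to 23.9 ± 13.9 CPM, and Tead4, a transcription factor of the trophectoderm, from 0.132 to 38.9 ± 8.86 CPM (8.09 ± 1.73, adjusted p = 0.0064).

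Adjusted over the list alone, the counts were 37 lower for maternal transcripts, 21 lower and 1 higher for zygotic 2-cell genes, 73 higher for ribosomal proteins, 20 higher and 4 lower for ribosome biogenesis, 24 higher and 5 lower for oxidative phosphorylation, 13 higher for the proteasome, 7 higher for histones and 12 higher and 2 lower for lineage regulators. Camera gave adjusted p of 6.43e-19, 3.58e-10, 6.43e-19, 0.000369, 2.11e-05, 0.000131, 0.0236 and 0.0018 for these lists in that order. The maternal list (adjusted p = 0.0196 with an estimated correlation) and the lineage list (0.026) held, and the others did not (0.145, 0.431, 0.452, 0.145, 0.145 and 0.716). Their medians kept their sign with the DESeq2 size factors, with −3.20 for maternal transcripts and 0.89 for lineage regulators.

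Other lists did not pass camera between the separated stages. Heat shock genes had 5 higher and 2 lower of 44 (adjusted p = 0.401, median 0.58 and mean −0.01), with Hspa8 up 3.37 ± 0.46, Dnajb4 down at −7.08 ± 1.54, and Hsp90ab1 up 2.21 ± 0.51 but not passing without separated 4-cell embryo 3 (adjusted p = 0.0601). In the G2/M list 5 of 52 fell (adjusted p = 0.335), Cks1b by −1.81 ± 0.29 and Nusap1 by −2.34 ± 0.39. The S phase list had 1 higher and 3 lower of 62 (adjusted p = 0.641), with Cdc6 up 2.39 ± 0.46 and the licensing inhibitor gene Gmnn down at −1.38 ± 0.33. Among Hippo and YAP genes (2 higher and 1 lower of 26, adjusted p = 0.755) Wwc2 fell from 211 ± 34.99 to 18.3 ± 11.1 CPM (−3.52 ± 0.56). Adhesion genes had 1 higher, Gja1 (3.29 ± 0.74), and 2 lower of 43 (adjusted p = 0.965). For cholesterol and lipid genes (1 higher and 1 lower of 28, adjusted p = 0.998) Insig1 fell by −2.81 ± 0.71, a call lost without separated 4-cell embryo 3 or 4 (adjusted p up to 0.0698).

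Of 80 chromatin genes 2 fell (adjusted p = 0.952), of 31 p53 targets 1 rose and 2 fell (adjusted p = 0.998), of 26 stress genes 1 rose (adjusted p = 0.693), and of 27 mitochondrially encoded genes 2 fell (adjusted p = 0.24). Among the latter mt-Cytb fell by −0.88 ± 0.25 (adjusted p = 0.0324), a call lost without separated 2-cell embryo 3 or separated 4-cell embryo 2, 3 or 4 (adjusted p up to 0.106). Of 5 sex-linked genes 1 rose (list adjusted p = 0.937), and none of 5 sperm genes passed (adjusted p = 0.755). Adjusted over the list alone, the counts higher and lower were 6 and 3 for heat shock, 0 and 5 for G2/M, 1 and 3 for S phase, 2 and 1 for Hippo, 2 and 4 for adhesion, 1 and 1 for cholesterol, 0 for chromatin, 1 and 2 for p53 targets and 1 and 0 for stress genes. The p53 targets had a median of 0.35 (0.28 with bounds) and a mean of −0.16, with the test pointing higher, and adhesion genes 0.03 and −0.16, with the test pointing lower, and the adhesion median was −0.02 with the DESeq2 size factors.

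In total 1568 of 14119 genes passed between the separated stages (904 higher and 664 lower). The count went to 711 with the replicate block, 2543 without the batch term, 3220 with DESeq2 and 3869 with each blastomere as a library. The share higher, 57.7%, was 38.9% with DESeq2, 44.3% with the stricter filter, 44.9% with the compared groups alone and 49.2% without separated 4-cell embryo 6 or 7. In 1254 of the genes called the stages did not overlap. Chance gives this for 3.57% of unselected genes, which again is no measure for genes picked for the difference. The count was 811 without separated 4-cell embryo 4, 962 without embryo 3 and 991 without embryo 2, and simulated 4-fold and 16-fold changes were recovered in 8% and 46% of genes. With limma voom Omt2a did not pass (adjusted p = 0.563), and of the genes named 10 of 16 with the largest changes and 23 of 49 list examples passed in every setting. Genes higher in both stage comparisons numbered 415 (48.9 by independence), those lower in both 419 (33.2) and those opposite 2. Both comparisons share 1 fit, its dispersion per gene and its filter, so the numbers by independence are no fair measure of chance overlap. The log2 fold changes had a correlation of 0.53 across genes, which are not independent replicates. Whether the change between stages differs between intact and separated embryos was tested as an interaction, and 0 of 14119 genes passed (edgeR, 1228 at an unadjusted p under 0.05, 523 with DESeq2 and 2 with limma voom).

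**Figure D2:**
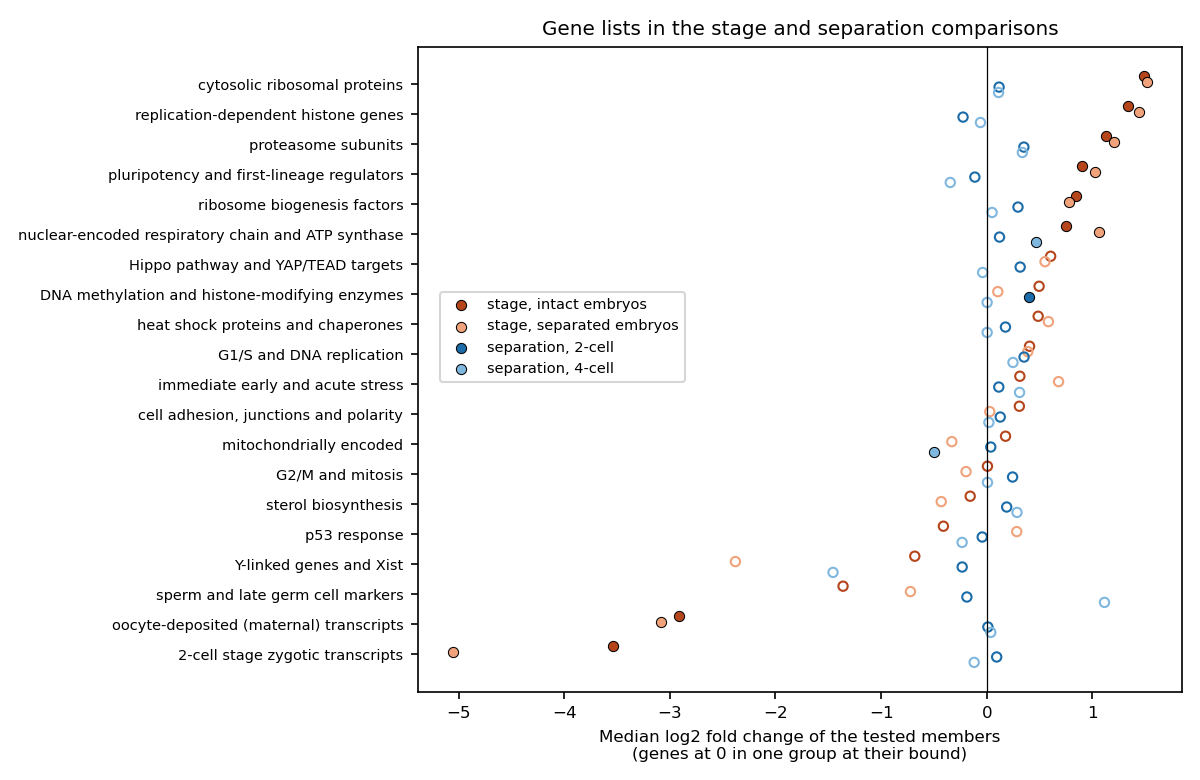
Median log2 fold change of 20 fixed gene lists in the 4 comparisons (colours), with genes without counts in a group at their bound, filled where camera gave an adjusted p under 0.05 and open elsewhere. Maternal transcripts (−2.91 and −3.09) and zygotic 2-cell genes (−3.54 and −5.06) are lower and ribosomal proteins (1.49 and 1.52) higher at the 4-cell stage, while most medians for separation lie near 0, where 9 at the 2-cell and 7 at the 4-cell stage change sign with the DESeq2 size factors.

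Between separated and intact 2-cell embryos 2 genes passed, and 0 with the compared groups alone or with the replicate number as a block. Mast3 had no count in intact embryos (n = 5) and 7.14 ± 4.23 CPM in separated ones (n = 5), at least 95.9-fold higher (adjusted p = 0.0247), with separated embryo 3 at 0.534 CPM. Idh3b, a subunit of mitochondrial isocitrate dehydrogenase, had 1 count against 1650 counts, 10.3 ± 10.4 CPM, a ratio of 357 (64.01 to 14110, adjusted p = 0.0247). Both were chosen after their values were seen, since the rule for named genes leaves them out at this level. Neither passed without intact embryo 1, and Mast3 also not without separated embryo 2 (adjusted p up to 0.07). Cyclin E1 (Ccne1) was at 77.5 ± 23.0 CPM in intact and 168 ± 39.7 CPM in separated embryos (log2 1.12 ± 0.28), the rRNA processing gene Mphosph10 at 165 and 276 CPM, and the proteasome gene Psma3 at 298 and 471 CPM (0.66 ± 0.22), with separated embryo 4 at 667 CPM. None of these passed (adjusted p = 0.244 each), nor did Nr5a2 (0.93 ± 0.34, adjusted p = 0.264), Tet1 (1.38 ± 0.56, adjusted p = 0.325) or Zscan4f (−1.18, adjusted p = 0.881). Among list members that were lower, Rrp1 went from 11.9 ± 8.34 to 0.1695 ± 0.379 CPM (−6.01 ± 1.39) and did not pass (adjusted p = 0.213), though it did under 6 of 20 alternatives. Ndufs1 went from 9.01 ± 8.22 to 1.04 ± 0.584 CPM (−3.11 ± 0.95, adjusted p = 0.244) and passed under 1 of 20.

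No member of a fixed list passed over all genes at the 2-cell stage. Adjusted over the list alone, 1 ribosome biogenesis gene was lower and 1 S phase gene higher. Of 20 lists, the 80 chromatin and DNA methylation genes alone passed camera (adjusted p = 0.0346, median 0.40, 65 of 80 above 0). That call did not hold with an estimated correlation (camera adjusted p = 0.37). The list did pass fry (adjusted p = 0.0145). It also passed camera with the replicate number as a block, at the preset correlation (adjusted p = 0.0244). The DESeq2 size factors moved the median of all genes by −0.20 here and that of the chromatin list to 0.17, with 50 of 80 above 0. With edgeR 2 of 14119 genes passed, against 1481 at an unadjusted p under 0.05, 493 with DESeq2 and 8 with limma voom. Both genes were without overlap, which chance gives for 0.794% of unselected genes, no measure for genes picked by the test. The count ranged from 0 without intact embryo 1 to 7 without intact embryo 2 or separated embryo 5, was 1 without separated embryo 2, 3 without intact embryo 5, 4 without intact embryo 3 or separated embryo 1 or 4, and 5 without intact embryo 4. With a median 95% half-width of 1.66 in log2 for genes of at least 10 CPM, 0% of simulated 2-fold and 20% of 4-fold changes were recovered.

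At the 4-cell stage the F-box gene Fbxw18 lay nearest to the threshold, at 15.6 ± 11.99 CPM in intact (n = 4) and 0.299 ± 0.129 CPM in separated batch 1 embryos (n = 3), a log2 fold change of −5.68 ± 0.90 that did not pass (adjusted p = 0.0551), though it did under 4 of the alternatives. The Krüppel-like factor gene Klf5 was at 106 and 288 CPM (1.44 ± 0.50), the complex I gene Ndufb6 at 199 and 433 CPM (1.12 ± 0.35), the cytochrome c oxidase gene Cox5a at 781 and 1337 CPM (0.78 ± 0.30), and Wwc2 at 63.0 and 18.3 CPM (−1.78 ± 0.53), each with adjusted p = 0.801. No list member passed over all genes. Adjusted over the list alone, 1 maternal transcript was higher and 1 lower. Of 20 lists, nuclear genes of oxidative phosphorylation passed camera as higher in separated embryos (adjusted p = 0.00154, median 0.47, 69 of 80 above 0), and mitochondrially encoded genes as lower (adjusted p = 0.000877, median −0.50, 26 of 27 below 0). Neither held with an estimated correlation (camera adjusted p = 0.37 and 0.615) or passed fry (adjusted p = 0.0505 and 0.155). Both passed camera with the replicate number as a block, at the preset correlation (adjusted p = 0.00972 and 0.000164). Both medians kept their sign with the DESeq2 size factors (0.33 and −0.64), which moved the median of all genes by −0.13.

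With edgeR 0 of 14119 genes passed between intact and separated 4-cell embryos, against 844 at an unadjusted p under 0.05, 379 with DESeq2 and 13 with limma voom. The count was 1 without intact embryo 3 or separated embryo 4, and chance gives groups without overlap for 5.71% of genes. The half-width was 2.01 and simulated 4-fold changes were recovered in 6% of genes, so most simulated changes of that size were missed. Across genes the separation effects at the 2-cell and 4-cell stages had a correlation of 0.006.

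Blastomeres of an embryo resembled each other more than blastomeres of other embryos. At the 2-cell stage the mean Pearson correlation across 6724 genes was 0.518 between sisters and 0.456 between embryos, a difference of 0.0624 (exact permutation p = 0.001058, one-sided, the smallest that 945 groupings can give, 5 pairs). At the 4-cell stage the difference within batches was 0.0332 (permutation p = 1e-05, the smallest that 100000 permutations give). It was 0.556 against 0.527 in batch 1 (exact permutation p = 0.000173) and 0.870 against 0.831 in batch 2 (exact permutation p = 0.0286, the smallest that 35 groupings give). The sizes depend on the genes used, with 0.1161 at the 2-cell and 0.03754 at the 4-cell stage for genes of at least 100 CPM and 0.03843 and 0.02162 for those of at least 1 CPM. Over another set of genes, those with a mean of at least 10 CPM over the blastomeres of both stages, the mean sister correlation subtracted from 1 was 0.388 ± 0.0309 in 2-cell (n = 5) and 0.297 ± 0.159 in 4-cell embryos (n = 5), a difference that did not pass (exact permutation p = 0.405, two-sided). The 4-cell mean pools 0.398 to 0.425 in batch 1 with 0.114 and 0.1345 in batch 2. With genes of at least 1 CPM the difference, −0.1014, did pass (exact permutation p = 0.0238). With genes chosen over batch 1 alone it was 0.408 against 0.388 (exact permutation p = 0.321, n = 5 and 3).

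Differences between embryos were seen for named genes as well. Dppa3, a maternal protein that guards DNA methylation in the zygote, averaged 14630 ± 990 CPM over the sisters of separated 2-cell embryo 3 and 31810 ± 56.0 CPM in embryo 4 (edgeR adjusted p = 0.0411). Znhit3 averaged 1076 ± 29.9 CPM in embryo 3 and 4733 ± 744 CPM in embryo 4 (adjusted p = 0.0416). The predicted genes Gm9519 and Gm9, chosen after their values were seen, were the other genes that passed of 11996, with 0.077 and 0.169 CPM in embryo 1. Hprt (adjusted p = 0.0557), Med27, Sycp3, Cenpi and Pnp (0.077 each) did not pass. Cenpi averaged 0.0156 CPM in embryo 1 and 72.4 to 164 CPM in the others, and Pnp 0.0955 CPM in embryo 3 and 94.3 to 181 CPM in the others. Without embryo 3, 4 or 5 the 2-cell count was 0. In simulated data this 2-cell test gave 39 false calls of 11996 genes with 1 setting of the dispersion and 5 with the other, so 4 calls lie within its false calls.

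At the 4-cell stage 103 of 10911 genes passed for differences between embryos of a batch. The centrosomal gene Cep89 averaged 344 ± 42.9 CPM over the 4 blastomeres of embryo 2 and 29.5 ± 4.29 CPM in embryo 4 (adjusted p = 0.000394). Levels of the named genes are compared within batch 1 here, where most of the named genes, though not most of the 103, passed. Tested within each batch, Cep89, H2ax, Omt2b, mt-Co1, Npm1 and Clk1 passed in batch 1 (adjusted p up to 0.0355). Rb1cc1 (0.05825) and Polr2k (0.07401) did not, and none of the named genes passed in batch 2 (adjusted p of at least 0.1517). The histone variant gene H2ax was near 0 in all blastomeres of embryo 2 (0.0597 ± 0.119 CPM) and averaged 75.8 and 89.9 CPM in embryos 3 and 4. The maternal transcript Omt2b was at 2088 ± 195 CPM in embryo 2 and at 454 and 292 CPM in embryos 3 and 4, and mt-Co1 at 7735 CPM against 3689 and 3696 CPM. Embryo 4 was above embryos 2 and 3 for Rb1cc1 (1406 CPM against 520.1 and 642 CPM) and Npm1 (6307 CPM against 3498 and 3899 CPM). Clk1 (31.4 CPM in embryo 2, 371 CPM in embryo 4) and Polr2k (1290 CPM in embryo 2, 691 and 716 CPM in embryos 3 and 4) also passed. Within batch 1 alone 11 of 7215 genes passed and within batch 2 alone 92 of 11582, and of the 103 genes 9 passed in batch 1, 17 in batch 2 and 77 in neither. The count was 33 without embryo 2 and 54 without 4. It was 21 without 6 and 23 without 7, which takes the whole batch 2 comparison out of the test and so says nothing on a single embryo, and simulated 4-fold differences were recovered in 12% of genes with 1 setting of the dispersion and 6% with the other.

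**Figure D3:**
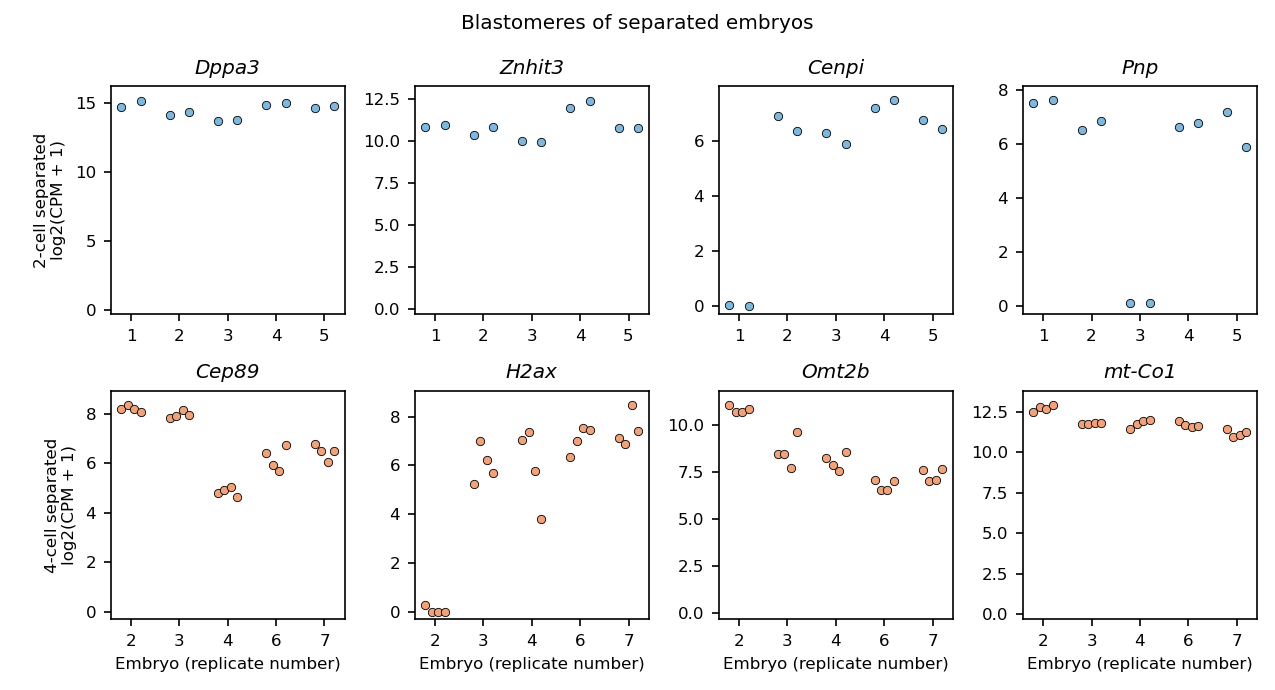
Level of 8 of the genes named for differences between embryos, of which Cenpi and Pnp did not pass, as log2 of CPM (not TMM-normalised) plus 1 for each blastomere (points) of each separated embryo (columns), with 2-cell embryos for Dppa3, Znhit3, Cenpi and Pnp and 4-cell embryos for Cep89, H2ax, Omt2b and mt-Co1. For H2ax the blastomeres of embryo 2 are at 0 to 0.223 CPM and those of the other 4-cell embryos, which lie apart within an embryo too, at 13.1 to 353 CPM.

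Gene groups also differed in how much sisters vary around the level of their embryo. Ribosomal protein genes varied less than genes of the same level at the 2-cell stage, at the 0.06 percentile of 10000 matched lists (at most 0.34 with any embryo left out). At the 4-cell stage they were at 6.82, from 0.48 without embryo 4 to 17.19 without embryo 3, with 1.09 in batch 1 and 0 in batch 2. Mitochondrially encoded genes varied more (99.83 and 99.46, at least 96.92 and 97.31 with any embryo left out), with 94.5 in batch 2. Matched lists draw each gene singly, so the percentiles of all lists do not allow for members that move together. The mitochondrial share of counts differed between the sisters of 2-cell embryos 1 (24.5 and 15.2%) and 2 (30.1 and 19.7%). It differed less in embryos 3, 4 and 5 (24.7 and 20.5% in embryo 5), and its part in the percentile was not tested. Nuclear genes of oxidative phosphorylation were at 64.55 at the 2-cell stage (6.69 without embryo 3) and at 0.02 at the 4-cell stage (at most 1.31 with any embryo left out). Within the 4-cell batches they were at 3.79 in batch 1 and 0.05 in batch 2. The lineage regulators were at 93.7 in 2-cell and 53.8 in 4-cell embryos, with 86.4 in batch 1 and 99.9 in batch 2. The genes varying most for their level were Ift74, Zfp873 and Zfp677 at the 2-cell stage, Ggps1 and Retn in batch 1 and Tmem37 and Myc in batch 2. Between batch 2 sisters, Myc ranged from 12.46 to 238 CPM in embryo 6 and from 0.14 to 114.61 CPM in embryo 7. In the same order, Sox21 ranged from 0.87 to 81.1 and from 0 to 41.1 CPM. Nanog ranged from 0.04 to 17.85 and from 0.99 to 55.9 CPM, and Nr5a2 from 559 to 699 and from 522 to 742 CPM. Sox21, Nanog and Nr5a2 were taken from the lineage list, outside the rule for named genes. For the 4-cell lineage list the percentile was 43.1 without embryo 2 and 92.3 without embryo 4, and for the 2-cell list 34.4 without embryo 3 and 43.3 without embryo 5, so single embryos decide both.

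Marker genes of other cells had counts in all groups. Cumulus and granulosa markers summed to 14.1 CPM on average in intact 2-cell and 15.8 CPM in intact 4-cell embryos, blood markers to 28.9 and 12.3 CPM, sperm markers to 76.2 and 23.6 CPM, and oviduct markers to 41.1 and 13.5 CPM. Kitl alone made up most of these cumulus sums (12.1 and 14.5 CPM) and Cfap126 most of the oviduct sums (25.3 and 9.72 CPM). The top blood gene, Hba-a1, was at 11.4 and 5.90 CPM. The top sperm genes were Ldhc (30.0 CPM, 2-cell) and Odf2 (11.2 CPM, 4-cell). In 2-cell, batch 1 4-cell and batch 2 4-cell blastomeres the cumulus markers were at 27.8, 15.6 and 7.30 CPM, blood markers at 25.7, 22.7 and 14.5 CPM, sperm markers at 71.3, 34.3 and 28.1 CPM, and oviduct markers at 49.96, 8.42 and 2.14 CPM. The highest sum in a library was 170 CPM, for sperm markers in a batch 1 4-cell blastomere. The cumulus, blood and oviduct lists had 4, 3 and 4 genes that could be tested, under the 5 needed for a list test.

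**Figure D4:**
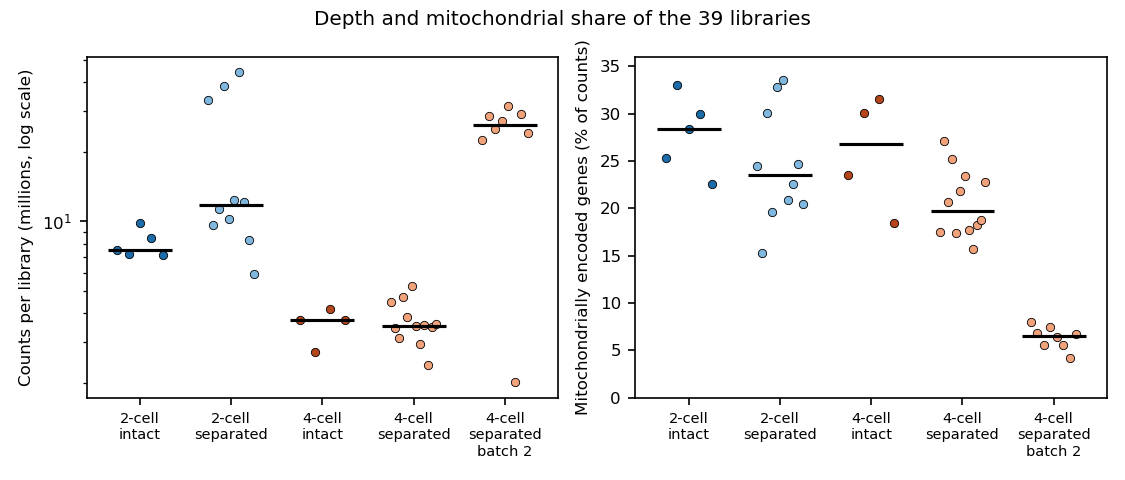
Left, counts per library in M, units of 1e+06 (log scale), and right, percent of counts from mitochondrially encoded genes, for 5 sets of libraries, with 1 point per library and a line at the median. Batch 2 blastomeres of separated 4-cell embryos have the highest median depth (26.1 M) and 6.35% mitochondrial counts on average, against 20.5% in batch 1.

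Depth per library was 7.16 to 9.89 M counts in intact 2-cell embryos, 5.93 to 44.05 M in 2-cell blastomeres, 2.74 to 4.19 M in intact 4-cell embryos, 2.40 to 5.23 M in batch 1 blastomeres and 2.02 to 31.6 M in batch 2 blastomeres of 4-cell embryos. Batch 2, which holds separated 4-cell embryos 6 and 7 only, differed from batch 1 in 286 of 14119 genes (38 higher and 248 lower, or 13.3% higher, against 26.1% of 280 with the DESeq2 size factors and 46.7% of 229 without the mitochondrially encoded and the 10 most abundant other genes), so 4-cell separated levels above are those of the 3 batch 1 embryos. That count was 64 without embryo 6 and 112 without embryo 7, where the lone embryo left in batch 2 is assumed to vary like those of the other groups. Batch 2 holds 1 group only, so stages and separation could not be compared within it. In libraries thinned to 2.02 M counts, 8092 ± 561 genes were detected per blastomere in batch 1 and 11966 ± 588 in batch 2.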

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

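All tests on batch 2, other than the batch contrast of the main fit, and all tests on genes near 0 were chosen after the data were seen. The counts for other groupings of the embryos, the gene length test and the test on the share of lower genes in batch 2 were chosen after their own results were seen, and the remaining tests before theirs.

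Values far from the others of their group were sought in 20 groups of library measures, of which 2 had one, and in 288 groups of named-gene levels, of which 19 had one, where chance gives about 1 in 20. Of 8 batch 2 blastomeres, blastomere 2 of separated 4-cell embryo 7 had 2.019 M counts (units of 1e+06), against 22.4 to 31.6 M in the others. The normalization factor of separated 2-cell embryo 5 was 1.048, against 0.882 to 0.913 in the others. In separated 2-cell embryo 4, Tcl1 was at 654.9 CPM (others 1688 to 2316), Psma3 at 667 CPM (397 to 442), Rbm41 at 6.504 CPM (0 to 0.0674) and Mfap2 at 0.1182 CPM (56.6 to 177). In the other separated 2-cell embryos, Mast3 was at 0.534 CPM in embryo 3 (6.54 to 11.7), mt-Nd2 at 19950 CPM in embryo 3 (11930 to 13300), Rpl21 at 219.1 CPM in embryo 5 (288 to 307) and Klf5 at 162.5 CPM in embryo 2 (84.0 to 92.6). In intact 2-cell embryos, Gtsf2 was at 110.3 CPM in embryo 2 (50.3 to 57.3), Psmb4 at 48.62 CPM in embryo 4 (26.9 to 29.9), Cdc6 at 18.98 CPM in embryo 1 (35.2 to 44.4), Cox5a at 386.4 CPM in embryo 3 (677 to 782), Mrps18a at 9.181 CPM in embryo 5 (0 to 0.138) and Ssmem1 at 0 CPM in embryo 5 (4.39 to 12.9). Intact 4-cell embryo 4 had the lowest Cdc6 (57.95 CPM, others 216 to 243), Psma6 (748.2 CPM, 1043 to 1099) and Psma3 (382.4 CPM, 615 to 661), and intact embryo 3 the lowest Igbp1 (0.372 CPM, 27.7 to 31.8). Ccdc93 was at 0.07235 CPM in separated 4-cell embryo 2 (10.5 to 27.5).

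Batch 2 differed from batch 1 in 286 genes (64 without embryo 6 and 112 without embryo 7, with the spread then taken from the other groups), of which 86.7% were lower. Depth was argued against, since 343 genes passed after embryo totals were thinned to the smallest, 85.1% of them lower. A few genes taking most of the counts were argued against as the source of the count, since 229 genes passed without the mitochondrially encoded and the 10 most abundant other genes, but the share of lower genes then went to 53.28% while the median of all genes moved by 0.51 in log2, so the excess of lower genes depends on the scaling and composition stays open for it. Gene length stays open as a candidate explanation: the lower genes had a median exonic length of 1467 nt against 3712 nt in matched sets (percentile 0 of 10000, and again 0 with list members left out), and a difference in fragmentation or priming was not tested further. Batch 2 holds separated 4-cell embryos only, so no biological explanation was tested.

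In batch 2 the lineage regulators varied more between sister blastomeres than matched genes (29 genes, percentile 99.95). This set was picked after its value was seen, out of 4 sets and 18 lists, and in the same batch the cholesterol list reached 99.96, the stress list 99.2, the p53 targets 99.1 and the zygotic 2-cell genes 98.9. Depth was argued against, since the percentile was 99.99 after thinning to the shallowest blastomere. Dependence on 1 library stays open, since the percentile was 92.94 without blastomere 4 of embryo 7 and 94.98 without blastomere 1, so the pattern may rest on single cells. The labels name no lineage group, so no biological explanation was tested.

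Some genes were under 1 CPM in every sister of 1 embryo and averaged at least 50 CPM over the blastomeres of the others. Not every other embryo had to express the gene: Gm26703 counted for 2-cell embryos 1, 3, 4 and 5. The Y-linked gene Eif2s3y counted for 2-cell embryos 4 and 5. At the 2-cell stage there were 146 such pairs of gene and embryo, against a median of 88 over groupings, and in batch 1 of the 4-cell stage 20 against 12. Independent dropout (exact permutation p = 0.001058 at the 2-cell and 0.004329 at the 4-cell stage) and depth (exact permutation p = 0.001058 and 0.01177 after thinning) were argued against. Sister libraries alike in their share of genes near 0 were argued against at the 2-cell stage (exact permutation p = 0.001058 for the ratio to the expected number), and at the 4-cell stage they stay open as a possible explanation (exact permutation p = 0.06926). Strain or donor variants and reads shared between paralogs were not tested, and the design gives no group, so no biological explanation was tested.

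For the stage comparisons chance is argued against as the source of the counts. The 1469 genes of intact embryos (798 without intact 4-cell embryo 5, 808 without 3 and 898 without 1) compare with at most 43 in 99 other groupings. The 1568 of separated embryos (811 without separated 4-cell embryo 4, 962 without 3 and 991 without 2) compare with at most 10 in 55 others. In each, 1 grouping, the real one, gave as many, the smallest share that 100 and 56 groupings can give. For separation at the 2-cell stage chance cannot be excluded: 24 of 100 groupings gave at least the 2 genes of the real one (0 without intact embryo 1 and 7 without intact embryo 2 or separated embryo 5), with a median of 1 and a highest other of 14 genes. That highest count is several times the real one, which could point to a structure among these embryos or be the largest of 99 chance counts, and neither was tested. For separation at the 4-cell stage (edgeR 0 genes, 35 of 35 groupings as large, highest other 2, 844 at an unadjusted p under 0.05, 379 with DESeq2, 13 with limma voom) and the interaction (edgeR 0 genes, 100 of 100, highest other 5, 1228 unadjusted, 523 with DESeq2, 2 with limma voom) a real count of 0 fixes the outcome, so these counts say nothing on chance. Among 12 groupings with DESeq2, the real one included, 9 gave at least the real 493 genes for separation at the 2-cell stage. At the 4-cell stage 6 gave at least the real 379, and for the interaction 3 at least the real 523, the real grouping again included. The highest others were 572, 432 and 582, so chance cannot be excluded for these DESeq2 counts. For embryo differences at the 4-cell stage chance is argued against for the count. It is not for each gene, since 77 of the genes called passed in neither batch alone. The 103 genes (33 and 54 without embryo 2 and 4) compare with at most 6 in 39 other groupings. The real grouping alone gave as many, the smallest share that 40 groupings can give. Without embryo 6 or 7 that count was 21 and 23, since batch 2 then has no pair of embryos to compare. At the 2-cell stage the 4 genes compare with at most 1 in 39 other groupings, but 0 passed without embryo 3, 4 or 5 and simulated data gave 5 and 39 false calls, so chance is not excluded for these calls.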

How the results depend on the processing

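The alternatives for the batch comparison, each embryo left out of the list tests, the variability of the lineage, ribosomal protein, mitochondrial and oxidative phosphorylation lists with an embryo left out or by batch, the alternatives for the lineage list in 2-cell embryos, and the embryo differences by batch were chosen after seeing the data.

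Stage counts, 1469 in intact and 1568 in separated embryos, went to 737 and 711 with the replicate number as a block, 3047 and 3220 with DESeq2, and 715 and 3869 with each blastomere as a library, to 2844 with limma voom in intact and 2543 without the batch term in separated embryos. The percent higher moved from 52.01 to 64.3 with voom, 41.7 with DESeq2 and 38.0 with the compared groups alone in intact embryos, and from 57.7 to 38.9 with DESeq2, 44.3 with the stricter filter and 44.9 with the compared groups alone in separated ones. Separation at the 2-cell stage (edgeR 2, 1481 unadjusted) gave 104 without a filter, 0 with the compared groups alone or the replicate block, 1 after thinning totals, 493 with DESeq2, 8 with voom and 107 by blastomere. Of these 107 genes 1 was higher and 0 were shared with the main test. Taking each blastomere as a library moved the median of all genes for separation by −0.91 at the 2-cell and −1.11 at the 4-cell stage. The counts by blastomere thus carry a shift across genes. DESeq2 on the 10 2-cell embryos alone gave 8. Separation at the 4-cell stage (edgeR 0, 844 unadjusted) gave 11 without a filter, 1 with the stricter filter, 379 with DESeq2, 13 with voom and 3 by blastomere, and the interaction (edgeR 0, 1228 unadjusted) 38, 1, 523 and 2 with the first 4 of these. Embryo differences at the 2-cell stage went from 4 to 14 with the stricter filter and 729 with DESeq2, and at the 4-cell stage from 103 to 978 with DESeq2 and 11 within batch 1 alone (92 within batch 2). The sister spread difference was −0.1014 with CPM of at least 1 (exact permutation p = 0.0238) against −0.0903. The lineage percentile, 53.8 at the 4-cell stage, was 65.32 after thinning, 82.23 with CPM of at least 1, 86.42 in batch 1 and 99.95 in batch 2, and 97.35 with CPM of at least 1 at the 2-cell stage. Of 80 list tests 19 passed, 4 with an estimated correlation, 19 with the replicate block and 24 with fry, 17 of them shared with the main test. Between intact stages the zygotic list passed fry (adjusted p = 0.000142), as did heat shock (0.000115), S phase (8.98e-05) and chromatin (0.00112), which did not pass camera. For 4-cell separation, oxidative phosphorylation (0.0505) and mitochondrially encoded genes (0.155) did not pass fry. For all of these the cause was not tested.

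With each embryo left out, counts ranged from 798 to 1431 (stage, intact), 811 to 1525 (stage, separated), 0 to 7 and 0 to 1 (separation, 2-cell and 4-cell), 0 to 2 (interaction), 64 to 201 (batch), 0 to 4 and 21 to 101 (embryo differences, 2-cell and 4-cell) and 17 to 20 (lists). The lowest came without intact 4-cell embryo 5 (798), separated 4-cell embryo 4 (811), intact 2-cell embryo 1 (0) and separated 4-cell embryo 6 (64 and 21, where batch 2 keeps 1 embryo), and the 2-cell embryo count was 0 without embryo 3, 4 or 5. Sister similarity, 0.0624 and 0.0332, ranged from 0.05598 to 0.07475 and from 0.03027 to 0.036 (0.1161 and 0.03754 with CPM of at least 100, 0.03843 and 0.02162 with at least 1), sister spread from −0.1305 to −0.0631, and lineage percentiles from 43.09 (without embryo 2) to 92.32 (without 4) at the 4-cell and from 34.35 (without 3) to 98.18 (without 4) at the 2-cell stage. Percentiles of variability ranged from 0 to 0.34 and from 0.48 (without 4) to 17.19 (without 3) for ribosomal proteins (6.82 with all embryos, 1.09 in batch 1 and 0 in batch 2), from 96.92 to 99.93 and from 97.31 to 99.82 for mitochondrially encoded genes (94.5 in batch 2), and from 6.69 (without 3) to 81.69 (without 2) and from 0 to 1.31 for oxidative phosphorylation (3.79 in batch 1 and 0.05 in batch 2), at the 2-cell and 4-cell stage. Of all comparison values, 80 were scored as moved and 1 as stronger, while 173 kept their side of the threshold or stayed within 1.5 times. The 173 include comparisons without a called gene in either setting. Of the values for single genes and lists 5704 kept their side, 107 became stronger, 296 weaker and 0 reversed. Reversal was scored only for genes and lists called in the main test. A gene not called there could change sign and still count as kept or stronger, so the 0 covers called genes and lists alone. For batch, the percent higher moved from 13.3 to 26.1 with DESeq2 size factors, which moved the median of all genes by 0.24, to 25.1 with sisters thinned and to 46.7 without abundant genes, which moved it by 0.51. The median 95% half-width between intact stages was 4.66 in log2 for genes under 10 CPM and 1.81 above, and whether depth sets it was not tested, with 1797 genes called after totals were thinned against 1469.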

Other observations

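No test of this part was chosen after its result was seen, and the genes were those of the fixed sex-linked list.

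In separated 2-cell embryo 3, blastomere 1 had 607 counts of Y-linked genes, with Eif2s3y at 42.6 CPM, and blastomere 2 had 5, with Eif2s3y at 0 CPM. In separated 2-cell embryos 1 and 2 both blastomeres had Y-linked counts (1017 to 9645), and in separated 4-cell embryo 4 all 4 blastomeres had them (104 to 263). Among 21 pairs of embryos with the same number in different groups, the correlation of residual levels was −0.055 to 0.025, and 0 pairs exceeded 0.1, so the numbers show no pairing of embryos.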
